A study of Chlorocebus aethiops with 36 samples.

How the data were processed

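Liver biopsies of 12 male African green monkeys were measured on a human Affymetrix expression array (HG-U133 Plus 2.0), so the probes were designed on human transcripts and met transcripts of another primate. Per the labels, 6 animals received a control anti-miR oligonucleotide and 6 received anti-miR-33, each at 5 mg/kg under the skin. Each animal was sampled 3 times, at week -5 (baseline, before treatment), at week 4 of treatment on chow, and at week 12 after 8 weeks of a high carbohydrate, moderate cholesterol diet. The 36 arrays therefore form 6 groups of 6, and the arm of a baseline array was taken from the animal's later labels. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled with an Enzo kit.

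The authors deposited a table of 54675 probe sets in log2 units, which the submitters' processing notes credit to RMA, a method that corrects the background, normalizes between arrays and summarises the probes of a probe set. The version of RMA, and whether all 36 arrays were normalized in a single run, are not given in the sources used here. The deposited log2 values carried 2 decimals and ran from 2.41 to 15.07, and the medians of the arrays lay between 4.42 and 4.51. A shift shared by most transcripts of an array would have been removed by such a normalization. The number of arrays per group limits the precision of every value. All 36 columns were matched to samples by their identifiers, and 0 columns were left unused.

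Gene symbols came from the platform annotation. Of the probe sets, 41097 had 1 gene, 1801 had several and 11777 were not listed there and stayed unnamed; 62 of all probe sets were the array maker's controls. Probe sets with several genes or none were left out of the gene tests. For each of 19775 genes the probe set of highest mean over all arrays was used, and probe sets with a mean below the median of all probe sets (4.459 on the log2 scale) were left out, which gave 13634 tested genes. Of these, 5534 had more than 1 probe set above the filter. For a named gene that changed by over 2 standard errors, another probe set was taken to disagree where it had the opposite sign or under 50% of the change, and its value is given in the account of that comparison. Symbols follow an annotation that can be old. A probe that mismatches the monkey transcript gives a lower value in every group, so levels were compared between groups for a probe set and never between probe sets.

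All 36 arrays were fitted together in limma 3.58.1 (R 4.3.3) with 6 group means and the animal as a random block, whose estimated correlation was 0.151. The pairing rests on the animal identifiers in the labels. As a check of it, each of the 12 week 4 arrays was matched to the animal whose baseline and week 12 arrays, averaged, it resembled most. Over 200 genes chosen on those other times, 12 of 12 matched their own animal. Moderated tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05; every adjusted p of a gene comes from this limma fit. There were 10 planned comparisons: anti-miR-33 minus control at each of the times, the differences between arms in the change between times, and the changes from baseline and from week 4 to week 12 within each arm. The changes from baseline to week 4 within each arm were added after the data were seen. Errors of single genes are standard errors from the fit.

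There were 25 gene lists, tested with limma's camera with a preset correlation between genes of 0.01, on values adjusted for the animal correlation, with Benjamini-Hochberg adjustment over all lists and the planned comparisons. They comprised miR-33 targets, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, bile acid synthesis and transport, targets of liver X receptors, lipoproteins, glucose metabolism and insulin signalling, AMP-activated kinase, interferon response, acute phase, xenobiotic metabolism, endoplasmic reticulum stress, oxidative phosphorylation, cell cycle and immediate early genes. The other lists held markers of hepatocytes, macrophages, lymphocytes, plasma cells, neutrophils and blood, stellate cells and fibrosis, endothelium, cholangiocytes, and fat and muscle. The miR-33 targets were genes remembered from earlier reporter or cell work and were not chosen on these samples. Camera was also run with an estimated correlation. As a further check added after the data were seen, the list's mean per animal was tested by an exact two-sided permutation, of the arm over the animals or of the sign of the change within animals. The smallest p that these can give is 0.00216 between arms and 0.0312 within an arm. Samples, tests, lists and the rule for named genes were fixed before the data were examined.

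The genes named for each comparison followed that rule. They were the 10 called genes of largest change in each direction, or the 3 of smallest p in a direction without calls, fixed genes of lipid metabolism, and up to 4 members of smallest adjusted p for a described list, or the 2 of smallest p where none passed. Genes named outside it are said to have been chosen after their values were seen. Of the fixed genes, CYP7A1 lay below the filter and was not tested, and some others are not reported here.

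RNA quality was read from the array maker's control probe sets for the 3′ and 5′ ends of GAPDH and ACTB, as the 3′ minus 5′ difference in log2 averaged over both genes, where a larger value means fewer transcripts labelled to the 5′ end. This value was also used as a covariate, an alternative added after the data were seen. The fit was tested on simulated data with the real genes, array number and animal correlation, and 200 changed genes of 13634. For anti-miR-33 against control at week 12 it recovered 73.1% of genes changed by 0.5 on the log2 scale, 97% of those changed by 1 and 100% of those changed by 1.5, and 7.7% of its calls were false. For the change from baseline to week 12 in control animals it recovered 76.1%, 97% and 100%, and 3.7% of its calls were false. Of 100 simulated lists of 20 independent unchanged genes, 2% had a camera p under 0.05 in the week 12 comparison, as had 100% of 20 lists shifted by 0.3. Real genes vary together, which this simulation left out.

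Alternatives were other filters, every probe set tested, quantile normalization or centring of the deposited values, a trend in the variance, array weights, the animal left out or as a fixed block, the replicate number as a block, each week fitted alone, and each animal left out in turn. A further alternative left out a week 4 control array, replicate 1, whose diet label names the high carbohydrate diet although the other week 4 labels name chow. The labels give the week 4 arrays a run of array numbers of their own, while baseline and week 12 share a run. A batch and week 4 therefore cannot be told apart in the changes from or to week 4, and it cancels in comparisons between arms. A planned search for miR-33 seed sites was not run because no 3′ untranslated sequences were used here.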

Results

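Gene expression was measured in liver biopsies of 12 male African green monkeys on 36 arrays. An anti-miR is a synthetic oligonucleotide that binds a microRNA and blocks it. The microRNA miR-33 is encoded within the SREBF genes and represses, among others, the cholesterol exporter ABCA1 and genes of fatty acid oxidation. Of the animals, 6 received a control anti-miR and 6 received anti-miR-33, and each was sampled at baseline, at week 4 on chow and at week 12 after 8 weeks of a high carbohydrate, moderate cholesterol diet. Animals are numbered within each arm by their replicate number at weeks 4 and 12. Across genes within pairs of arrays, where genes are not independent replicates, Pearson r ran from 0.951 to 0.99, and at most 2.29% of values were identical in a pair. Values are on the log2 scale, and differences between arms are anti-miR-33 minus control.

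The value from which RNA quality was read differed between the times. The 3′ minus 5′ difference of the GAPDH and ACTB control probe sets was 2.57 ± 0.43 at baseline, 1.94 ± 0.41 at week 4 and 1.83 ± 0.16 at week 12 (SD, n = 12). At week 4 GAPDH exceeded ACTB on every array, while neither gene was consistently higher at baseline or week 12. For anti-miR-33 animal 2 they were 2.68 and 2.83 at baseline, 2.57 and 1.86 at week 4, and 1.89 and 1.94 at week 12. The fall to week 4 was thus larger by ACTB than by GAPDH, and the cause was not tested. From baseline to week 12 the average of both genes fell by 0.59 ± 0.15 (SE) in control animals, in 6 of 6 (exact permutation p = 0.0312, two-sided). In anti-miR-33 animals it fell by 0.89 ± 0.23, in 5 of 6 (exact permutation p = 0.0625). Between arms it differed by 0.25 at baseline, 0.03 at week 4 and -0.04 at week 12, with exact permutation p of 0.327, 0.913 and 0.665. The first principal component of all arrays, with 20.1% of the variance, had a Pearson r of -0.917 with this value over the 36 arrays, which share animals and times. The plot of the 3′ minus 5′ value shows these shifts for each animal.

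**Figure D1:**
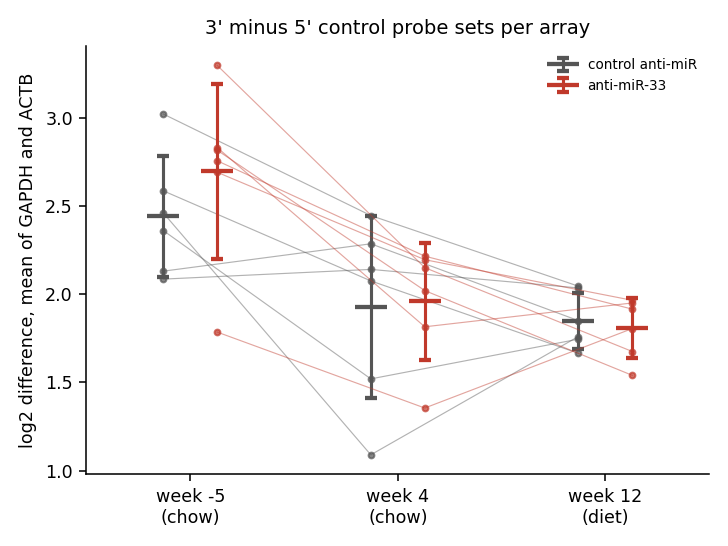
The 3′ minus 5′ difference of the GAPDH and ACTB control probe sets (log2, vertical axis) on each array, by week of biopsy and arm (grey, control anti-miR; red, anti-miR-33). Thin lines join the arrays of an animal and thick bars are means ± SD (n = 6); the mean over all animals was 2.57 at baseline and 1.83 at week 12.

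Before treatment, the arms were compared to see what differed beforehand. The largest evidence was for KIT, a receptor tyrosine kinase of mast and progenitor cells, with a difference of -0.94 ± 0.20 (SE), and for GRK3, a receptor kinase, with -0.55 ± 0.13. SULT1A1, a sulfotransferase, differed by 0.46 ± 0.12, TNFRSF25 by 0.28 ± 0.07, SNRPF-DT by 0.34 ± 0.08 and ZBTB44 by -0.39 ± 0.11. Other probe sets of GRK3 stood at -0.11 and 0.11, and 1 each of SULT1A1, TNFRSF25 and ZBTB44 at 0.10, -0.16 and -0.02. None of these passed the test: limma called 0 of 13634 genes, the adjusted p of KIT was 0.545, and 531 genes had an unadjusted p under 0.05, where about 682 would by chance. The miR-33 targets ABCA1 and CROT differed by -0.06 ± 0.17 and -0.08 ± 0.11. Of the 25 gene lists, only the endothelial markers passed, with 16 members tested and a mean difference of -0.13 (adjusted p = 0.0253, and adjusted p = 0.84 with an estimated correlation; exact permutation p = 0.223). None of its members passed over all genes or adjusted over the list alone. The call was absent without control animal 1, 3, 5 or 6 or anti-miR-33 animal 1 or 5, each of which left 0 lists, and its mean ran from -0.20 to -0.07 over the animals left out, while 4 lists passed without anti-miR-33 animal 4.

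At week 4 the arms were compared for the effect of anti-miR-33 on chow. ABCA1, the cholesterol exporter, stood at 8.20 ± 0.30 under anti-miR-33 and 7.64 ± 0.28 under control (SD, n = 6), a difference of 0.55 ± 0.17 (SE), or 1.46-fold. CROT, the peroxisomal carnitine octanoyltransferase, differed by 0.23 ± 0.11, and OSBPL6, an oxysterol-binding protein, by 0.73 ± 0.26 (other probe set at 0.24). These did not pass over all genes: limma called 0 of 13634 genes, the adjusted p of ABCA1 was 0.998, and 662 genes had an unadjusted p under 0.05. Adjusted over the list alone, ABCA1 passed among the 13 tested targets of liver X receptors, and 0 of the 20 tested miR-33 targets passed. The genes of smallest p were ASAP3 (0.42 ± 0.10), SELENOW (0.45 ± 0.11), PIN4 (0.35 ± 0.09), LCIIAR (-0.33 ± 0.08), GRK3 (-0.54 ± 0.13) and PYROXD1 (-0.39 ± 0.10), each with an adjusted p of 0.417. Another probe set of PIN4 stood at -0.02, and those of GRK3 at -0.16 and -0.09.

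Other fixed genes of lipid metabolism did not pass at week 4. SREBF1, the transcription factor that drives fatty acid synthesis and whose gene hosts miR-33b in primates, differed by 0.64 ± 0.42 (adjusted p = 0.998), with its other probe set at 0.04. SREBF2, the sterol regulator, differed by 0.13 ± 0.08, CPT1A, which carries fatty acids into mitochondria, by -0.18 ± 0.37, and HADHB, of the mitochondrial trifunctional protein, by 0.03 ± 0.16. NPC1, the lysosomal cholesterol transporter, differed by 0.14 ± 0.11, PRKAA1 by -0.01 ± 0.16, IRS2 by 0.09 ± 0.34, ABCB11, the bile salt export pump, by -0.02 ± 0.26, ATP8B1 by 0.11 ± 0.16 and SIRT6 by -0.04 ± 0.07. FASN, ACLY and ACACA, enzymes of fatty acid synthesis, differed by 0.26 ± 0.68, -0.06 ± 0.27 and 0.11 ± 0.12.

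Among the gene lists at week 4, the interferon response was lower under anti-miR-33. The mean of its 26 tested genes was 6.39 ± 0.16 under anti-miR-33 and 6.51 ± 0.17 under control (SD, n = 6), a difference of -0.12 (limma camera, adjusted p = 3.13e-04), and 3 of the 26 lay above 0. It was -0.08 without control animal 4 (adjusted p = 0.0485) or anti-miR-33 animal 4 (adjusted p = 0.0204). The adjusted p was 0.84 with an estimated correlation and the exact permutation p was 0.223. No member passed, with IFIT2 at -0.28 ± 0.12 and IRF7 at 0.33 ± 0.15. The miR-33 targets had a mean difference of 0.07 and a median of 0.01 (adjusted p = 0.314), with 10 of 20 above 0. Their mean ran from 0.03 to 0.10 over the animals left out, with the list called in 0 of 12 such fits. Fatty acid oxidation, at -0.09, and fatty acid synthesis, at 0.09, did not pass either (adjusted p = 0.0971 and 0.657). Fatty acid oxidation did pass without control animal 3 (-0.13) or 4 (-0.16) or anti-miR-33 animal 4 (-0.11) or 6 (-0.12), and fatty acid synthesis ran from 0.006 to 0.18 over the animals left out.

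**Figure D2:**
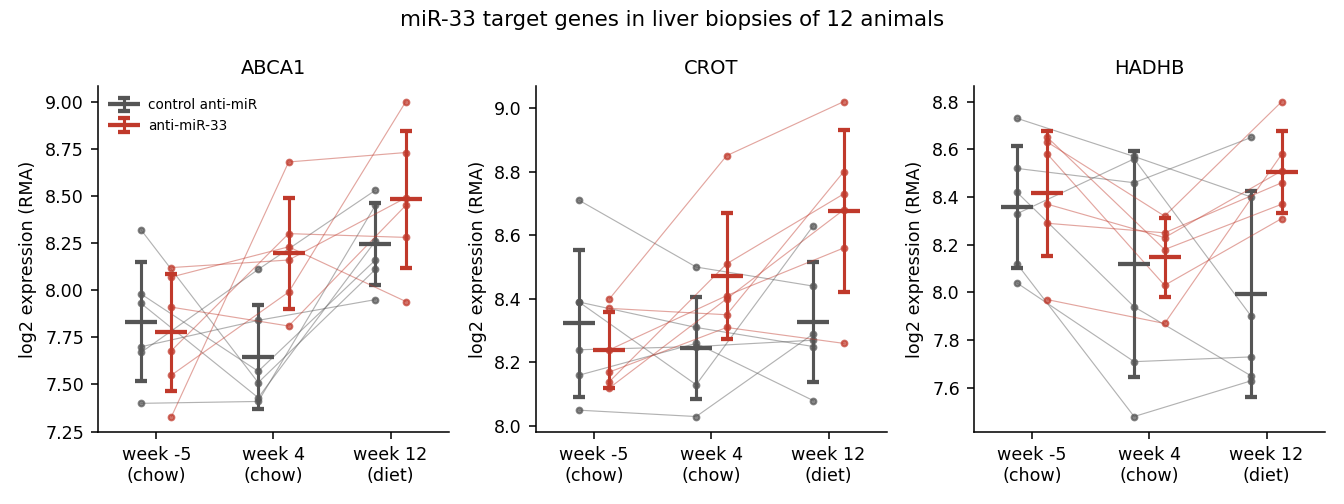
Expression (log2, vertical axes) of the miR-33 targets ABCA1, CROT and HADHB on each array, by week and arm (grey, control anti-miR; red, anti-miR-33); thin lines join the arrays of an animal and thick bars are means ± SD (n = 6). ABCA1 averaged 8.20 under anti-miR-33 and 7.64 under control at week 4, where the diet label of control replicate 1 differs from the rest, and HADHB 8.51 and 7.99 at week 12.

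At week 12, after the diet, 2 enzymes of fatty acid oxidation among the miR-33 targets had the smallest p of that list. CROT stood at 8.68 ± 0.25 under anti-miR-33 and 8.33 ± 0.19 under control (SD, n = 6), a difference of 0.35 ± 0.11 (SE), or 1.27-fold. HADHB stood at 8.51 ± 0.17 and 7.99 ± 0.43, a difference of 0.51 ± 0.16, or 1.43-fold. Adjusted over the list alone, CROT and HADHB passed, 2 of the 20 tested miR-33 targets and 2 of the 26 tested genes of fatty acid oxidation. Over all genes their adjusted p was 0.998. ABCA1 differed by 0.24 ± 0.17. Limma called 0 of 13634 genes, and 414 had an unadjusted p under 0.05. The smallest p values belonged to PLAAT2, a phospholipase and acyltransferase, at -0.70 ± 0.15, and PIN4, a prolyl isomerase, at 0.40 ± 0.09, both with an adjusted p of 0.313. Other probe sets of PLAAT2 stood at 0.10 and -0.14, and 1 of PIN4 at -0.04.

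The remaining genes of smallest p at week 12 were ATP2B2, a calcium pump, at 0.45 ± 0.10 (its 3 other probe sets at 0.10, -0.01 and 0.01), SELENOW, a selenoprotein, at 0.45 ± 0.11, LITAF at -0.41 ± 0.11 and FGF13 at -0.86 ± 0.24. The last 3 had stood at 0.41, -0.34 and -0.66 at baseline, before treatment, and PLAAT2, PIN4 and ATP2B2 at -0.12, -0.003 and -0.002. Among the fixed genes, CPT1A differed by 0.23 ± 0.37, PRKAA1 by 0.16 ± 0.16, NPC1 by 0.01 ± 0.11, IRS2 by -0.19 ± 0.34, ABCB11 by -0.10 ± 0.26, ATP8B1 by 0.07 ± 0.16 and SIRT6 by 0.04 ± 0.07. SREBF1 differed by -0.69 ± 0.42 (0.06 on its other probe set), SREBF2 by -0.04 ± 0.08, FASN by -0.52 ± 0.68 (0.08 on its other probe set), ACLY by -0.55 ± 0.27 (-0.14 on another) and ACACA by 0.05 ± 0.12, none of which passed.

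Of the gene lists, 9 of 25 passed at week 12 with the preset correlation. The interferon response was lower under anti-miR-33, at 6.47 ± 0.11 against 6.71 ± 0.23 (SD, n = 6), with 1 of 26 genes above 0 and a mean difference of -0.23 (limma camera, adjusted p = 8.45e-11; adjusted p = 0.273 with an estimated correlation; exact permutation p = 0.0519). OASL, an oligoadenylate synthetase-like protein, differed by -0.54 ± 0.18 (other probe set at -0.13) and OAS1, which activates RNA decay, by -0.43 ± 0.14, without passing. The miR-33 targets were higher, with 14 of 20 above 0, a mean of 0.12 and a median of 0.05 (adjusted p = 0.0399; adjusted p = 0.688 with an estimated correlation). Fatty acid oxidation was also higher, with 23 of 26 above 0 and a mean of 0.09 (adjusted p = 0.00185; adjusted p = 0.84 with an estimated correlation). Exact permutation p for these 2 lists was 0.275 and 0.442. The call of the miR-33 targets was kept in 4 of 12 fits that left out 1 animal each and was lost without control animal 1, 3, 4, 5 or 6 or anti-miR-33 animal 2, 3 or 4. Its mean then ran from 0.07, without control animal 3 (adjusted p = 0.198), to 0.19, without control animal 2. Fatty acid oxidation lost its call without control animal 5 (mean 0.03, adjusted p = 0.234), and its mean was 0.17, 0.06 and 0.15 without control animals 2, 3 and 6.

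The other 6 lists that passed at week 12 were of hepatocyte, acute phase, cell cycle, immediate early, macrophage and lymphocyte genes. Hepatocyte markers, with all 18 members above 0, and acute phase genes, with 15 of 16, had mean differences of 0.12 and 0.15 (adjusted p = 5.43e-07 and 2.29e-05). TTR, the plasma carrier of thyroid hormone, differed by 0.19 ± 0.09, and the fibrinogen chains FGB and FGA by 0.17 ± 0.09 and 0.22 ± 0.10. Cell cycle genes, with MCM2 at -0.21 ± 0.09, and immediate early genes, with DUSP1 at -0.73 ± 0.33 (others at -0.04 and -0.07) and JUN at -0.57 ± 0.27 (another at -0.25), had means of -0.15 and -0.27 (adjusted p = 0.0065 and 0.00314). Macrophage markers, with C1QA at -0.35 ± 0.14, and lymphocyte markers, with KLRB1 at -0.26 ± 0.13, had means of -0.12 and -0.10 (adjusted p = 0.00543 and 0.0232). For these 6 lists the adjusted p was 0.84 with an estimated correlation, exact permutation p ran from 0.0779 to 0.307, and 0 members passed over all genes or adjusted over the list alone. On the array of control replicate 5 the hepatocyte mean was 11.9 (other controls 12.31 to 12.52). Its highest value was 13.8 (other week 12 arrays 14.99 to 15.03), and the cause was not tested. Without that array 4 lists passed at week 12. Without control animal 5, 5 did, and the calls of hepatocyte (0.03), cell cycle (-0.08) and lymphocyte genes (-0.06) were lost. Cell cycle also lost its call without control animal 1 (-0.07) or anti-miR-33 animal 2 (-0.12), and lymphocyte markers without anti-miR-33 animal 5 (-0.09) or 6 (-0.08). Immediate early genes lost theirs without control animal 2 (-0.12) or 6 (-0.19) or anti-miR-33 animal 2 (-0.21) or 6 (-0.22), and macrophage markers without control animal 6 (-0.09) or anti-miR-33 animal 3 (-0.08) or 6 (-0.07). The acute phase mean was 0.10 without control animal 5 or anti-miR-33 animal 4, and the macrophage mean -0.19 without the latter.

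The lists that did not pass at week 12 were, with their mean differences and adjusted p, fatty acid synthesis (-0.16, 0.0946), cholesterol synthesis (-0.03, 0.719), bile acid synthesis and transport (0.03, 0.265), lipoproteins (0.01, 0.212) and AMP-activated kinase (-0.02, 0.88). Fatty acid synthesis did pass in 6 of 12 fits that left out 1 animal each, those without control animal 2, 5 or 6 or anti-miR-33 animal 2, 3 or 5. Its mean ran from -0.29, without control animal 6 (adjusted p = 5.59e-04), to 0.01, without control animal 4. Targets of liver X receptors had a mean of -0.03 and a median of 0.01 (adjusted p = 0.906), and glucose metabolism and insulin signalling a mean of 0.02 and a median of -0.01 (adjusted p = 0.958). Xenobiotic metabolism (0.03, 0.284), endoplasmic reticulum stress (0.09, 0.391) and oxidative phosphorylation (0.05, 0.0506) did not pass. Among the cell markers, plasma cells (-0.12, 0.302), neutrophils and blood (0.00, 0.52), stellate cells and fibrosis (-0.07, 0.207), endothelium (-0.08, 0.143), cholangiocytes (0.13, 0.142) and fat and muscle (-0.04, 0.58) did not pass. EPCAM, a bile duct marker, differed by 1.03 ± 0.29 (0.56 ± 0.29 at baseline) and APOA4, an apolipoprotein, by -0.51 ± 0.16. Over all genes neither passed (adjusted p = 0.998 for both), and adjusted over the list alone EPCAM passed among 9 cholangiocyte markers and APOA4 among 17 lipoprotein genes.

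The changes over time were then compared between the arms, which removes lasting differences between animals. From baseline to week 4 KIT had a difference in change of 1.28 ± 0.26 (SE, adjusted p = 0.289), ABCA1 of 0.61 ± 0.23 and CROT of 0.31 ± 0.14. KIT had already differed by -0.94 between the arms at baseline, so most of its value reflects the gap before treatment. From baseline to week 12 the difference in change was 0.43 ± 0.14 for CROT, 0.46 ± 0.21 for HADHB, 0.29 ± 0.23 for ABCA1 and -0.74 ± 0.55 for SREBF1. From week 4 to week 12 it was -1.32 ± 0.55 for SREBF1 (other probe set at 0.02), 0.49 ± 0.21 for HADHB, 0.41 ± 0.17 for PPARA, the receptor that induces fatty acid oxidation (2 of its other 4 probe sets at 0.14 and -0.10), -0.31 ± 0.23 for ABCA1 and -0.51 ± 0.12 for WNT2B. Limma called 0 of 13634 genes in each of these 3 comparisons, with 478, 299 and 487 genes at an unadjusted p under 0.05. With the animal as a fixed block, in place of the random one, KIT was the 1 gene called from baseline to week 4 (adjusted p = 0.0183).

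As lists, the difference in change passed for 2 lists from baseline to week 4, for 6 from baseline to week 12 and for 8 from week 4 to week 12. The interferon response had a difference in change of -0.12 to week 4 (adjusted p = 4.09e-04) and of -0.23 to week 12, with 0 of 26 genes above 0 (adjusted p = 1.37e-08; OASL -0.65 ± 0.23 with its other probe set at -0.16, RSAD2 -0.56 ± 0.21). Endothelial markers had a difference in change of 0.20 to week 4 (adjusted p = 0.0065; STAB2 0.50 ± 0.17). Most of it came from the arms before treatment. The endothelial mean was 7.00 under anti-miR-33 and 7.14 under control at baseline, against 6.52 and 6.45 at week 4. STAB2 already differed by -0.35 at baseline. From week 4 to week 12, 23 of 26 genes of fatty acid oxidation lay above 0, with a mean of 0.18 (adjusted p = 4.95e-05), and the difference in change from baseline to week 12 was 0.12 (adjusted p = 0.00991). Immediate early genes had differences in change of -0.41 to week 12 from baseline and -0.42 from week 4 (adjusted p = 4.62e-04 and 3.35e-04; FOS -1.67 ± 0.79, EGR1 -1.11 ± 0.51). The miR-33 targets did not pass; their means were 0.02, 0.06 and 0.04 in the 3 comparisons, and their medians -0.00, -0.01 and -0.00. No list passed with an estimated correlation, where the smallest adjusted p of these comparisons was 0.505, for the interferon response to week 12, and the smallest exact permutation p of a list that passed was 0.0693. Of the calls named here, the endothelial one to week 4 was lost without control animal 1 (0.13) or anti-miR-33 animal 5 (0.14), and without control animal 4 it was 0.30 and the interferon one -0.08. Fatty acid oxidation to week 12 from baseline was 0.18 without control animal 2 and lost its call without control animal 5 (0.03) or anti-miR-33 animal 1 (0.09) or 3 (0.06), and immediate early genes without control animal 6 (-0.25) or anti-miR-33 animal 6 (-0.26).

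Across genes, which are not independent replicates, the arm differences at week 4 and at week 12 had a Pearson r of 0.246. The 462 ways to split the 12 animals into the arms gave a median r of 0.302 (exact permutation p = 0.58, two-sided).

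**Figure D3:**
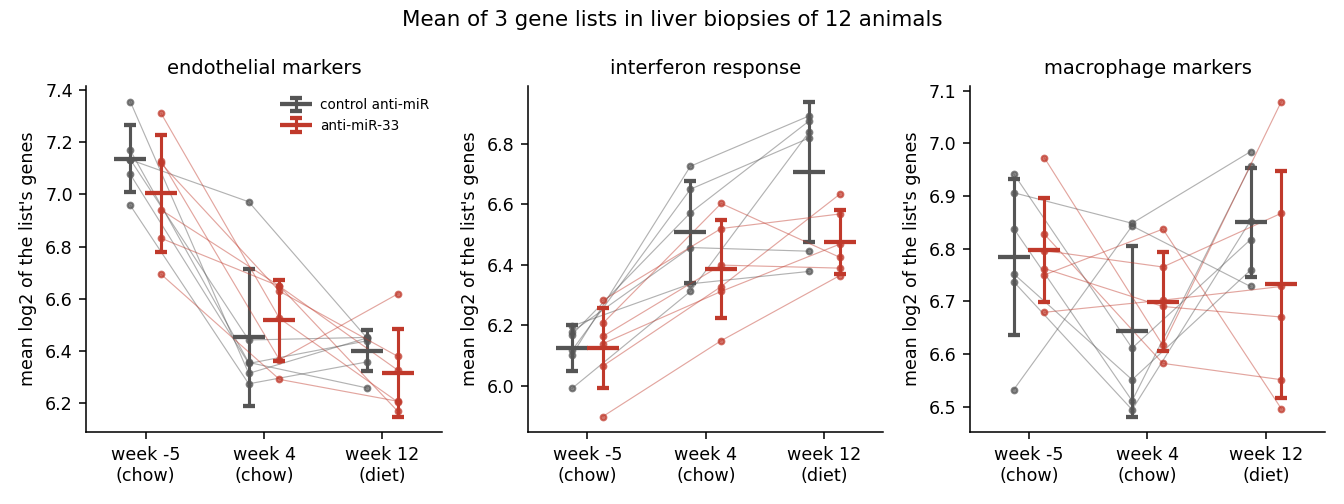
Mean log2 expression (vertical axes) of the endothelial marker, interferon response and macrophage marker lists on each array, by week and arm (grey, control anti-miR; red, anti-miR-33); thin lines join the arrays of an animal and thick bars are means ± SD (n = 6). In control animals from baseline to week 12 the endothelial mean fell by 0.74 and the interferon mean rose by 0.58; the diet label of control replicate 1 at week 4 differs from the rest.

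From baseline to week 12, with the diet, the control oligonucleotide and time together, SCD, ELOVL5, NR0B2, HLA-DRA and HLA-DMA rose and endothelial markers fell in the livers of control animals. SCD, the stearoyl-CoA desaturase, rose by 2.33 ± 0.35 (SE), or 5.04-fold, in 6 of 6 animals (limma, adjusted p = 2.77e-05), ELOVL5, a fatty acid elongase, by 1.31 ± 0.18 (other probe set at -0.02), and NR0B2, which represses bile acid synthesis, by 1.34 ± 0.21. HLA-DRA and HLA-DMA, of antigen presentation, rose by 1.65 ± 0.21 and 1.39 ± 0.24. EFNB2, an ephrin ligand of vessels, fell by 1.80 ± 0.19 (adjusted p = 8.77e-08), and CLEC4G, a lectin of sinusoidal endothelium, fell by 1.43 ± 0.15. Limma called 1297 of 13634 genes, 389 higher and 908 lower. With the 3′ minus 5′ value, which fell over the same interval, as a covariate, 494 were called, and 516 were called without control animal 3 and 661 without control animal 5.

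Further genes of largest increase were RGCC, DUSP1, a stress-induced phosphatase, GADD45B and the lipogenic genes SREBF1 and THRSP. RGCC rose by 2.35 ± 0.52, DUSP1 by 1.70 ± 0.31 with other probe sets at 0.35 and 0.09, GADD45B by 1.33 ± 0.26 with 1 of its others at 0.10, SREBF1 by 1.63 ± 0.39 and THRSP by 1.53 ± 0.44. SREBF1 was higher in 5 of 6 animals, with its other probe set at 0.16, and THRSP in 4 of 6. With the covariate the changes were 2.02 ± 0.60 for RGCC (adjusted p = 0.0501), 1.36 ± 0.45 for SREBF1 (0.0836) and 0.83 ± 0.46 for THRSP (0.365), with SE of 0.52, 0.39 and 0.44 before it. Genes of largest decrease included TIE1 (-1.65 ± 0.22), KIT (-1.61 ± 0.19), CETP, which transfers cholesteryl esters between lipoproteins (-1.57 ± 0.21), ADAMTS5 (-1.56 ± 0.25), FCN2, a lectin of complement (-1.54 ± 0.17, with its other probe set at 0.05), INMT (-1.40 ± 0.18), BEX1 (-1.38 ± 0.29) and HBB, beta globin from blood in the biopsy (-1.46 ± 0.32, with 1 of its others at 0.07).

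Genes of fatty acid synthesis, cholesterol synthesis and fatty acid oxidation were called in control animals. Of 20 tested genes of fatty acid synthesis, 6 rose and 0 fell, or 7 and 0 adjusted over the list alone, among them SCD, ELOVL5, SREBF1 and FADS2, a desaturase (0.62 ± 0.17, other probe set at 0.26). The list's mean change was 0.57 ± 0.25, above 0 in 4 of 6 animals (limma camera, adjusted p = 4.78e-05; adjusted p = 0.84 with an estimated correlation; exact permutation p = 0.125). It was 0.31 with the 3′ minus 5′ covariate, with which FADS2 stood at 0.58 and lost its call (adjusted p = 0.111). The change of FASN, the fatty acid synthase, was 1.28 ± 0.63 (-0.03 on its other probe set) and did not pass (adjusted p = 0.208). Of 20 tested genes of cholesterol synthesis, 3 fell and 0 rose, or 5 and 1 adjusted over the list alone. HMGCS1 fell by 1.11 ± 0.28, SQLE fell by 0.67 ± 0.19 and FDPS fell by 0.64 ± 0.20, and the list's mean was -0.13 (adjusted p = 0.289). That mean ran from -0.19 to -0.05 over the animals left out. With the covariate HMGCS1 stood at -1.05 ± 0.33 and SQLE at -0.72 ± 0.23 and lost their calls as the errors grew (adjusted p = 0.0646 and 0.0703), and the other probe set of SQLE stood at -0.06. Of 26 tested genes of fatty acid oxidation, 5 fell and 0 rose, or 7 and 0 adjusted over the list alone, with a mean of -0.21 (adjusted p = 0.0287; adjusted p = 0.891 with an estimated correlation). The smallest p belonged to ACAA1, the peroxisomal thiolase (-0.85 ± 0.18), ACAA2 (-0.57 ± 0.14, others at -0.05 and 0.09) and ECHS1 (-0.30 ± 0.08), and the list's call was lost without control animal 5 (-0.13).

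The lists of sterol and bile acid genes did not pass. For ABCA1, ABCG1, ABCG5, ABCG8 and SREBF2, transporters and regulators of sterols, the changes were 0.41 ± 0.16, 0.11 ± 0.10, 0.26 ± 0.17, 0.41 ± 0.15 and -0.06 ± 0.07, and none passed. Targets of liver X receptors, with a mean of 0.34 (adjusted p = 0.159), held the increase in SCD and SREBF1 and a decrease in NR1H3, the receptor itself (-0.55 ± 0.13). In the bile acid list, with a mean of 0.10 and a median of -0.01 (adjusted p = 0.573), ABCB11 rose by 1.02 ± 0.24 (0.52 with the covariate, adjusted p = 0.202), SLC10A1, the bile salt importer, by 0.32 ± 0.08, and CYP27A1 fell by 0.28 ± 0.07.

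Interferon, endothelial and stellate genes moved as groups in control animals. Of 26 interferon genes 18 rose and 0 fell, or 22 and 0 adjusted over the list alone, with a mean change of 0.58 ± 0.12, above 0 in 6 of 6 animals (limma camera, adjusted p = 3.22e-21; adjusted p = 0.0351 with an estimated correlation; exact permutation p = 0.0312). IFI6 rose by 0.94 ± 0.11, OASL by 1.09 ± 0.16 (other probe set at 0.33), RSAD2 by 0.98 ± 0.15 and OAS1 by 0.85 ± 0.13. Of 16 endothelial markers 11 fell and 0 rose, or 13 and 1 adjusted over the list alone, with a mean of -0.74 ± 0.06 (adjusted p = 3.27e-14; adjusted p = 0.143 with an estimated correlation; exact permutation p = 0.0312). Among them were the scavenger receptor STAB1 (-1.05 ± 0.11) and ENG (-1.22 ± 0.13, other probe set at 0.08). Of 17 stellate cell and fibrosis markers 6 fell and 0 rose, or 7 and 0 adjusted over the list alone, with a mean of -0.37 (adjusted p = 8.4e-05; adjusted p = 0.84 with an estimated correlation), among them BGN (-0.88 ± 0.11, with 1 of its others at -0.04) and PDGFRA (-0.71 ± 0.14). The 3′ minus 5′ value fell over this interval; with it as a covariate the endothelial mean was -0.62 and the interferon mean 0.54.

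The cell cycle and immediate early lists also passed in control animals. Of 13 cell cycle genes 4 rose, or 5 adjusted over the list alone, with a mean of 0.28 (adjusted p = 0.00212; adjusted p = 0.84 with an estimated correlation). These were TYMS, which rose by 0.70 ± 0.16, MCM2 by 0.37 ± 0.09, CDK1 by 0.45 ± 0.13 and RRM2 by 1.06 ± 0.32. Of 14 immediate early genes, which respond to handling of a biopsy, 2 rose, or 5 adjusted over the list alone, DUSP1 and IER3 (0.64 ± 0.19), with a mean of 0.38 (adjusted p = 0.0116; adjusted p = 0.84 with an estimated correlation). That call was lost without control animal 2 (0.27) or 6 (0.22). Macrophage markers did not pass (mean 0.07, adjusted p = 0.443), although CTSS, a cathepsin, rose by 0.76 ± 0.15 (other probe set at 0.10) and LYZ, lysozyme, by 0.70 ± 0.17. Hepatocyte markers had a mean of 0.01 and a median of -0.01 (adjusted p = 0.998).

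In anti-miR-33 animals over the same interval, SCD, ELOVL5, ABCA1 and CROT rose and endothelial markers fell. SCD rose by 2.11 ± 0.35 (SE), or 4.33-fold, in 6 of 6 animals (limma, adjusted p = 9.11e-05), and ELOVL5 by 1.24 ± 0.18, with its other probe set at 0.00. CETP fell by 1.54 ± 0.21, EFNB2 by 1.49 ± 0.19, TIE1 by 1.49 ± 0.22, FCN2 by 1.40 ± 0.17 with its other probe set at 0.01, CLEC4G by 1.27 ± 0.15 and HBB by 1.29 ± 0.32 with 1 of its others at 0.04. ABCA1 rose by 0.70 ± 0.16 (adjusted p = 0.00217), in 5 of 6 animals, and CROT by 0.43 ± 0.10 (adjusted p = 0.0022), in 6 of 6. The differences from the change in control animals were 0.29 ± 0.23 and 0.43 ± 0.14 and did not pass. Limma called 2223 of 13634 genes, 939 higher and 1284 lower. With the 3′ minus 5′ value as a covariate 137 were called, and 1207, 1357 and 1374 were called without anti-miR-33 animals 4, 5 and 6.

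Most of the largest increases in anti-miR-33 animals shrank with that covariate. PSAT1, of serine synthesis, rose by 1.64 ± 0.34 and stood at 0.06 with the covariate, CMAHP by 1.57 ± 0.25 and at 0.43, and SELENOT by 1.54 ± 0.26 and at 0.33. YIPF5 rose by 1.54 ± 0.24 and stood at 0.49 with it, GATM, of creatine synthesis, by 1.49 ± 0.26 and at 0.60, NNT by 1.43 ± 0.24 and at 0.31, and ADH4, an alcohol dehydrogenase, by 1.27 ± 0.34 and at 0.18. Without the covariate, other probe sets of PSAT1 and ADH4 stood at 0.06 and 0.04, of GATM at 0.49 and 0.42, of NNT at 0.50 and 0.39 and of YIPF5 at -0.21, 0.51 and 0.27. IGFBP2 rose by 1.52 ± 0.40 and stood at 1.85, and YJEFN3 rose by 1.28 ± 0.24 and stood at 1.10. SCD stood at 1.21 ± 0.40 with the covariate (adjusted p = 0.159), ELOVL5 at 0.63 ± 0.19 (0.0879), ABCA1 at 0.55 ± 0.21 (0.23) and CROT at 0.50 ± 0.13 (0.0499). Of the largest decreases, CETP, EFNB2, TIE1, FCN2, CLEC4G and HBB kept their calls with it, as did PTH1R (-1.27 ± 0.16), TCF4 (-1.27 ± 0.16, with 2 of its others at -0.37 and 0.01) and ECRG4 (-1.42 ± 0.24), and BEX1 (-1.33 ± 0.29) did not.

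The gene lists of anti-miR-33 animals were led by cell markers. Endothelial markers fell in 11 of 16 genes and rose in 0, or 13 and 0 adjusted over the list alone, with a mean of -0.69 ± 0.10 (adjusted p = 3.9e-11; adjusted p = 0.273 with an estimated correlation; exact permutation p = 0.0312), with ENG at -1.17 ± 0.13 (other probe set at 0.03) and STAB1 at -0.83 ± 0.11. Stellate cell and fibrosis markers fell in 9 of 17, or 10 adjusted over the list alone, with a mean of -0.47 (adjusted p = 1.78e-05; adjusted p = 0.84 with an estimated correlation; BGN -0.94 ± 0.11, COL1A2 -0.89 ± 0.16). Another probe set of BGN stood at -0.08, and those of COL1A2 at -0.12 and 0.03. Interferon genes rose in 10 of 26 and fell in 0, or 14 and 1 adjusted over the list alone, with a mean of 0.35 ± 0.06 (adjusted p = 5.43e-07; adjusted p = 0.688 with an estimated correlation), with IFI6 at 0.63 ± 0.11, IFI44 at 1.03 ± 0.24 and IFIT1 at 0.88 ± 0.21. With the 3′ minus 5′ covariate the endothelial mean was -0.51 and the interferon mean 0.28.

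Metabolic lists of anti-miR-33 animals followed. Fatty acid synthesis rose in 5 of 20 genes, as it did adjusted over the list alone, with a mean of 0.46 (adjusted p = 0.0065; adjusted p = 0.84 with an estimated correlation), which was 0.06 with the 3′ minus 5′ covariate. The changes of SREBF1, 0.90 ± 0.39 (adjusted p = 0.118; other probe set at 0.07), and FASN, 1.20 ± 0.63 (adjusted p = 0.206), did not pass. Oxidative phosphorylation rose in 7 of 24, as adjusted over the list alone, with a mean of 0.14 (adjusted p = 0.0081; NDUFV2 0.59 ± 0.10, COX7B 0.40 ± 0.08) and -0.04 with the covariate. Acute phase genes rose in 4 of 16 and fell in 1, or 5 and 1 adjusted over the list alone, with a mean of 0.22 (adjusted p = 0.0164; LBP 0.99 ± 0.29, CRP 0.72 ± 0.25). Endoplasmic reticulum stress genes rose in 3 of 17 with 1 lower, or 4 and 1 adjusted over the list alone, with a mean of 0.25 (adjusted p = 0.0221; SEL1L 0.64 ± 0.14 with 1 of its others at 0.27, ATF4 -0.44 ± 0.11). For these 3 lists the adjusted p was 0.84 with an estimated correlation. The fatty acid synthesis call was lost without anti-miR-33 animal 5 (0.32), and the acute phase and endoplasmic reticulum stress calls without anti-miR-33 animal 1 (0.23 and 0.25) or 4 (0.14 and 0.12). Cholesterol synthesis fell in 4 of 20 genes, as adjusted over the list alone (HMGCS1 -1.06 ± 0.28, FDPS -0.79 ± 0.20, SQLE -0.66 ± 0.19, HSD17B7 -0.49 ± 0.12; other probe sets of HMGCS1 and SQLE at -0.35 and 0.08), with a mean of -0.16 that did not pass (adjusted p = 0.221). Fatty acid oxidation held 5 genes that rose and 5 that fell (mean -0.09, adjusted p = 0.736), and the miR-33 targets 3 and 2 (mean 0.06, adjusted p = 0.281).

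The calls of the arms from baseline to week 12 overlapped, although the arms hold separate animals. There were 275 genes higher and 674 lower in both, where independent lists would share 26.8 and 85.5, and 0 genes were called in opposite directions. Across genes, which are not independent replicates, the changes of the arms had a Pearson r of 0.836, and both arms share the fall of the 3′ minus 5′ value.

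**Figure D4:**
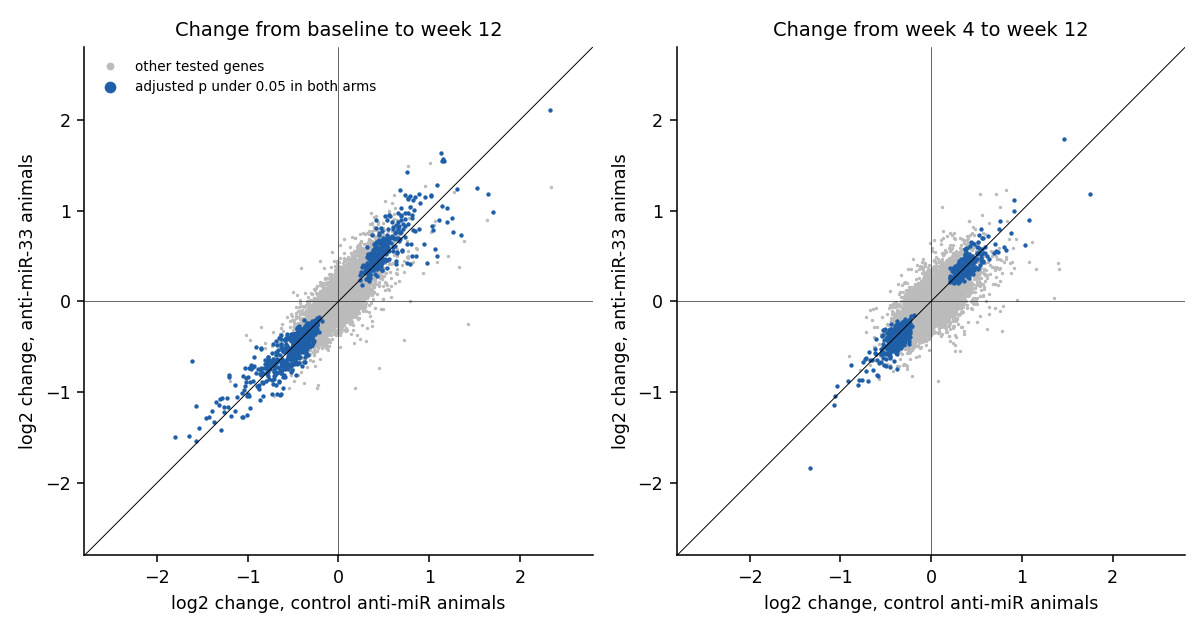
Log2 change of each tested gene in control animals (horizontal axis) against anti-miR-33 animals (vertical axis), from baseline to week 12 (left) and from week 4 to week 12 (right). Each point is a gene, blue points have an adjusted p under 0.05 in both arms, the line marks equal change, and Pearson r across genes was 0.836 and 0.735.

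From week 4 to week 12, the interval of the diet switch, SCD, SREBF1, NR0B2, ABCA1 and ELOVL5 rose and SQLE fell in control animals. SCD rose by 1.47 ± 0.35 (SE, adjusted p = 0.00862), SREBF1 by 1.36 ± 0.39 in 4 of 6 animals (its other probe set at -0.03), NR0B2 by 1.03 ± 0.21, ABCA1 by 0.60 ± 0.16 (adjusted p = 0.0166) and ELOVL5 by 0.72 (other probe set at 0.03). SQLE, the squalene epoxidase of cholesterol synthesis, fell by 0.75 ± 0.19 (its other probe set at -0.19). Limma called 1157 of 13634 genes, 551 higher and 606 lower. A batch of the week 4 arrays and the interval cannot be told apart. With the animal left out as a block 647 genes were called, and 740 were called without the week 12 array of control replicate 5, 604, 609 and 576 without control animals 2, 3 and 5.

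Other genes of largest increase were DUSP1 (1.75 ± 0.31, with other probe sets at -0.04 and -0.11), GADD45B (1.11 ± 0.26), HLA-DMA (1.08 ± 0.24), IL6ST, the receptor chain gp130 (1.08 ± 0.20), PFKFB3, which stimulates glycolysis (0.95 ± 0.24), YJEFN3 (0.94 ± 0.24) and DYNLL1 (0.92 ± 0.23). The largest decreases were of HBB (-1.33 ± 0.32), ANXA6 (-1.07 ± 0.16), TRIAP1 (-1.06 ± 0.13), FBXL17 (-1.03 ± 0.10, adjusted p = 1.45e-07), DLST (-0.91 ± 0.10), APP (-0.88 ± 0.17), RAB5C (-0.80 ± 0.09), FAAH (-0.79 ± 0.12) and PBX2 (-0.76 ± 0.10). Other probe sets stood at 0.19 for GADD45B, 0.34 for IL6ST, -0.09 for HBB, -0.08 for ANXA6, 0.00 and -0.17 for APP, -0.05 for RAB5C and -0.16 for PBX2. The changes of FASN, ABCG1, ABCG5, ABCG8 and SREBF2 were 0.64 ± 0.63, 0.17 ± 0.10, 0.35 ± 0.17, 0.04 ± 0.15 and 0.05 ± 0.07 and did not pass.

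Of the lists in control animals from week 4 to week 12, oxidative phosphorylation rose in 4 of 24 genes, or 6 adjusted over the list alone, with a mean of 0.16 (limma camera, adjusted p = 2.44e-04; NDUFA9 0.41, ATP5F1A 0.39). Immediate early genes rose in 2 of 14, or 5 adjusted over the list alone (mean 0.52, adjusted p = 0.00636), interferon genes in 3 of 26, as adjusted over the list alone (mean 0.20, adjusted p = 0.0105; PSMB9 0.78, GBP1 0.61 with its other probe set at 0.22). Macrophage markers rose in 2 of 16, as adjusted over the list alone (mean 0.21, adjusted p = 0.0164; LYZ 0.82, CD14 0.37). Neutrophil and blood markers fell in 2 of 8, HBB and AHSP (-0.23), both of red cells, or 3 adjusted over the list alone (mean -0.34, adjusted p = 0.0065; adjusted p = 0.688 with an estimated correlation). Endoplasmic reticulum stress rose in 1 of 17, HERPUD1 (0.51), or 3 adjusted over the list alone (mean 0.23, adjusted p = 0.043; adjusted p = 0.88 with an estimated correlation). Fatty acid synthesis rose in 3 of 20 and fell in 1, or 6 and 1 adjusted over the list alone (mean 0.39, adjusted p = 0.0444; adjusted p = 0.891 with an estimated correlation). For the first 4 of these lists the adjusted p was 0.84 with an estimated correlation. Without control animal 1, 4 of the 7 lists passed. Fatty acid synthesis kept its call in 6 of 12 fits that left out 1 animal each (lost without control animal 1, 3, 4 or 5 or anti-miR-33 animal 2 or 6; mean at least 0.31). Calls were also lost for endoplasmic reticulum stress without control animal 1 (0.21), 2 (0.14) or 6 (0.24), immediate early genes without 2 (0.39) or 6 (0.40), macrophage markers without 1 (0.16) or 3 (0.18) and interferon genes without 5 (0.13).

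**Figure D5:**
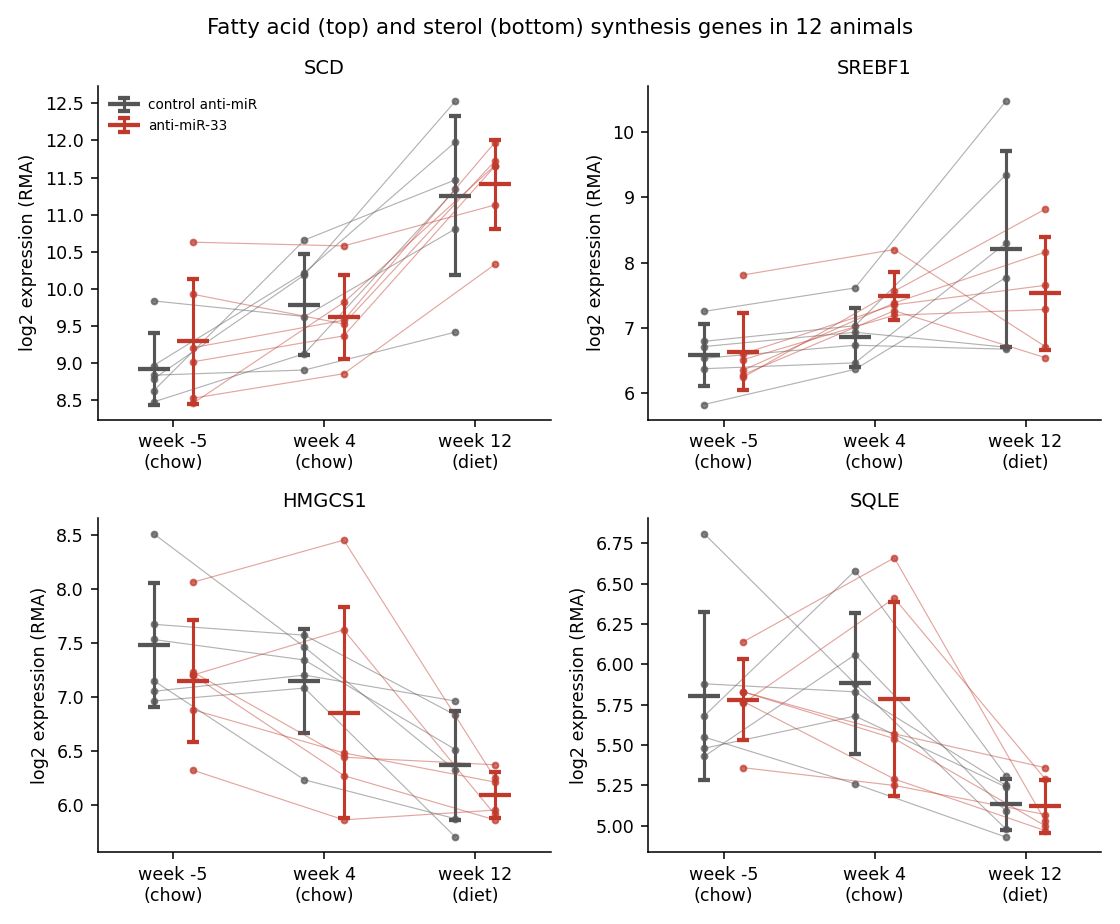
Expression (log2, vertical axes) of SCD, SREBF1, HMGCS1 and SQLE on each array, by week and arm (grey, control anti-miR; red, anti-miR-33); thin lines join the arrays of an animal and thick bars are means ± SD (n = 6). SCD averaged 8.93 at baseline and 11.26 at week 12 in control animals and 9.30 and 11.41 in anti-miR-33 animals; the diet label of control replicate 1 at week 4 differs from the rest.

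In anti-miR-33 animals from week 4 to week 12, SCD rose by 1.79 ± 0.35 (SE, adjusted p = 0.0013). HSPA5, the chaperone BiP, rose by 1.18 ± 0.27, HSPA13 by 1.11 ± 0.25 and MANF by 0.80, and INSIG1, which holds back the SREBP factors, rose by 1.04 ± 0.27 (1 of its others at 0.30). Of 20 tested genes of cholesterol synthesis 4 fell and 1, INSIG1, rose, or 5 and 1 adjusted over the list alone, and the list did not pass (mean -0.12, adjusted p = 0.221). SQLE fell by 0.67 ± 0.19 (other probe set at 0.04), FDPS fell by 0.70 and MVD fell by 0.40. The changes of ABCA1, 0.29 ± 0.16 (adjusted p = 0.234), and SREBF1, 0.04 ± 0.39 (adjusted p = 0.964), did not pass. Limma called 1705 of 13634 genes, 725 higher and 980 lower. A batch of the week 4 arrays and the interval cannot be told apart. There were 1048 genes called with the animal left out as a block, and 930, 1072 and 1034 without anti-miR-33 animals 2, 3 and 5.

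Further large increases in anti-miR-33 animals were of HPGD, which degrades prostaglandins (1.23 ± 0.33), DUSP1 (1.19 ± 0.31, with other probe sets at -0.13 and -0.17), INHBB (1.19 ± 0.33), DYNLL1 (1.00 ± 0.23), IL6ST (0.89 ± 0.20) and EPCAM (0.88 ± 0.27). Large decreases were of HBB (-1.84 ± 0.32), ANXA6 (-1.15 ± 0.16), TRIAP1 (-1.04 ± 0.13), FBXL17 (-0.94 ± 0.10), RAB5C (-0.93 ± 0.09, adjusted p = 6.33e-08), DLST (-0.88 ± 0.10), PPP1R1A (-0.88 ± 0.17), FAAH (-0.87 ± 0.12), PBX2 (-0.86 ± 0.10) and CYP1A1 (-0.86 ± 0.22). Disagreeing probe sets stood at 0.30 for HPGD, 0.29 for IL6ST, -0.06 for HBB, -0.09 for ANXA6, 0.10 for RAB5C, -0.25 for PPP1R1A and -0.35 and 0.04 for PBX2. For FASN, ABCG1, ABCG5, ABCG8 and SREBF2 the changes were -0.14 ± 0.63, 0.17 ± 0.10, 0.30 ± 0.17, 0.11 ± 0.15 and -0.11 ± 0.07 and did not pass.

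Of the lists in anti-miR-33 animals from week 4 to week 12, oxidative phosphorylation rose in 7 of 24 genes, or 9 with 1 lower adjusted over the list alone (mean 0.19, limma camera, adjusted p = 3.84e-05; ATP5F1A 0.50, NDUFB5 0.50). Endoplasmic reticulum stress genes rose in 5 of 17, or 8 with 1 lower adjusted over the list alone (mean 0.34, adjusted p = 0.00215). Endothelial markers fell in 3 of 16, as adjusted over the list alone (mean -0.20, adjusted p = 0.0381; ENG -0.62 with its other probe set at -0.14). The adjusted p was 0.84 with an estimated correlation for oxidative phosphorylation and endoplasmic reticulum stress, and 0.85 for the endothelial markers, whose call was lost without control animal 5 or anti-miR-33 animal 2, 3, 5 or 6, with means from -0.29 to -0.14 over the animals left out. Fatty acid oxidation rose in 3 genes, among them ETFDH (0.73), and fell in 2 of 26 (mean 0.14, adjusted p = 0.087, and 0.0440 without anti-miR-33 animal 5), and fatty acid synthesis rose in 2 and fell in 2 of 20 (mean 0.14, adjusted p = 0.599). The arms shared 241 genes higher and 376 lower from week 4 to week 12, where independent lists would share 29.3 and 43.6, and 0 were called in opposite directions.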

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

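In this part, the tests of 1 animal and of a baseline difference for the interferon list were chosen after the results were seen, and the exact permutation of list means was added after the data were seen. So were the counts of gene lists over splits at baseline and for the changes over time, and the counts of genes over splits for the changes from baseline to week 4.

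The interferon response list was lower under anti-miR-33 than control at week 12, by 0.23 on average, and its difference in change from baseline was also called with the preset correlation, but neither call held with an estimated one (adjusted p = 0.273 and 0.505). The difference does not rest on 1 animal as its whole cause, since 84.2% of it was kept without control animal 4, the most influential, and the value ran from -0.30 to -0.20 over the animals left out. Chance assignment of animals was not excluded, with an exact two-sided permutation p of 0.0519. A difference between the arms from before treatment stays undecided as a cause. It was 0 ± 0.06 (SE) at baseline, but the difference in change from baseline, -0.23 ± 0.13, lay within 2 standard errors of 0. Fewer immune cells, or an action of anti-miR-33 on interferon genes, direct or not, may be among the open explanations, as untested hypotheses found on the same data. Macrophage (-0.12) and lymphocyte markers (-0.10) were also lower at week 12 by the preset correlation, but not by an estimated one. Each call was kept in 9 of 12 fits that left out 1 animal. At week 4, when the interferon list was lower, these markers were not (macrophage 6.70 under anti-miR-33 and 6.64 under control, lymphocyte 5.56 and 5.525).

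Other lists also had a difference in change between the arms by the preset correlation of camera, anti-miR-33 minus control, and none passed with an estimated correlation. Those from baseline to week 4 were the interferon response (-0.12) and endothelial markers (0.20, after means of 7.00 under anti-miR-33 and 7.14 under control at baseline). To week 12 from baseline they were fatty acid oxidation (0.12), the interferon response (-0.23), oxidative phosphorylation (0.094), immediate early genes (-0.41), hepatocyte markers (0.089) and macrophage markers (-0.13). From week 4 to week 12 they were fatty acid oxidation (0.18), acute phase (0.062), immediate early genes (-0.42), hepatocyte markers (0.14), macrophage markers (-0.17), lymphocyte markers (-0.13), stellate cell and fibrosis markers (-0.16) and endothelial markers (-0.15). When each animal was left out in turn, the calls from baseline to week 4 were kept in 12 and 10 of 12 fits, in the order given, and those from baseline to week 12 in 9, 12, 9, 10, 9 and 10. The calls from week 4 to week 12 were kept in 12, 7, 12, 11, 9, 5, 6 and 4 of 12 fits, and the macrophage, lymphocyte, stellate and endothelial differences ran from -0.26 to -0.10, from -0.16 to -0.09, from -0.20 to -0.04 and from -0.24 to -0.09. Without control animal 5 the acute phase difference turned to -0.02, and those of hepatocyte markers were 0.006 from baseline and 0.05 from week 4.

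Splits of the animals into other arms bear on these counts. Limma called 0 genes between the arms at baseline, week 4 and week 12 and in the 3 differences in change, and a count of 0 is reached by all 100 drawn splits, so these splits decide nothing about chance; the highest other counts were 180, 195, 11, 10, 2 and 1. Genes were called in 14 of the 100 splits at baseline, 30 at week 4 and 18 at week 12. Counts of up to 180 and 195 where the arms gave 0 point to a structure of the samples other than the arms, and whether it lies in single animals or in genes that vary together was not tested. The lists called were 1, 1, 9, 2, 6 and 8, with as many in 94, 93, 29, 81, 36 and 12 of the 100 splits and highest other counts of 8, 10, 14, 7, 11 and 11. Chance cannot be excluded for any of these counts of lists.

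Within animals, the times were exchanged in all 32 ways. The real genes called from baseline to week 12 were 1297 in control and 2223 in anti-miR-33 animals (highest others 831 and 1708), and from week 4 to week 12 1157 and 1705 (166 and 82). Those from baseline to week 4 were 2465 and 2547 (994 and 911). In each of these 6 comparisons 1 of 32 exchanges, the real one, gave as many genes. The exact permutation p was thus 0.0312 in each, the smallest that 32 exchanges can give. It was not adjusted over the 6 comparisons, which share arrays. For the gene counts this argues against chance in each comparison taken alone, but does not exclude it. For the counts of lists, 7, 7, 7, 3, 3 and 3 in that order, as many came from 13, 12, 8, 23, 23 and 17 of 32 exchanges, with highest others of 9, 9, 12, 10, 7 and 7. Chance cannot be excluded for the list counts.

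An array stood apart from the other 5 of its group in 23 of 276 groups tested, over 46 measures, where chance marks about 1 in 20 groups, or 13.8 here. The value after each measure is the gap to the nearest array as a share of the group's range, which passed the critical value of Dixon's test. At week 12 control replicate 5 was lowest for lipoproteins (0.731; 9.48, the rest 9.87 to 10.02) and hepatocyte markers (0.667), and at week 4 control replicate 5 was lowest for targets of liver X receptors (0.714; 7.35, the rest 7.61 to 7.72). Control animal 4 at week 4 was highest for endothelial markers (0.759; 6.97, the rest 6.27 to 6.44). Anti-miR-33 animal 1 stood apart at baseline in xenobiotic metabolism (0.712), SREBF1 (0.771) and ATP8B1 (0.626). The same animal stood apart at week 4 in the bile acid list (0.772; 8.93, the rest 8.73 to 8.78), ACACA (0.769), SREBF1 (0.634) and NPC1 (0.632).

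Anti-miR-33 animal 4 stood apart at baseline in hepatocyte (0.638) and lymphocyte markers (0.628), at week 4 in immediate early genes (0.635; 7.38, the rest 6.68 to 6.94) and at week 12 in neutrophil and blood markers (0.745). Anti-miR-33 animal 6 stood apart at baseline in cholesterol synthesis (0.634) and at week 4 in stellate cell and fibrosis markers (0.641; 7.99, the rest 7.39 to 7.60) and SIRT6 (0.727). Further single arrays stood apart in ABCG1 (0.667, anti-miR-33 animal 2) and ACLY (0.70, anti-miR-33 animal 5) at week 12 and in CROT at week 4 (0.63, anti-miR-33 animal 3). At baseline SCD was highest in control animal 2 (0.64; 9.84, the rest 8.48 to 8.97) and SQLE in control animal 6 (0.674; 6.81, the rest 5.43 to 5.88).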

How the results depend on the processing

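The settings without the week 12 array of control replicate 5 and with the 3′ minus 5′ covariate, and the comparisons from baseline to week 4, were chosen after the data were seen. Over all alternatives, values of single genes gave the same direction and side of the threshold 19257 times, lost a call 899 times, gained one 71 times and reversed 5 times. Values of lists did so 1834, 218, 43 and 3 times, and counts stayed within 1.5 times of the reported count 471 times and left it 72 times. Limma called 0 genes between arms and in the differences in change under all alternatives, with 3 exceptions of 1 gene each. These were FGF9 at week 4 with no filter on dim probe sets (0.43 ± 0.08, adjusted p = 0.0295, at a mean of 3.81, below the filter), PIN4 at week 12 with every probe set tested (0.47 ± 0.08, adjusted p = 0.0342) and KIT from baseline to week 4 with the animal as fixed replicate block (1.28 ± 0.21, adjusted p = 0.0183). The r between the arm differences at week 4 and week 12 was 0.204 with no filter.

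With no replicate block 647 and 1048 genes were called from week 4 to week 12 in control and anti-miR-33 animals, and it moved no other gene count by over 1.5 times. The replicate number in the title as a block gave 0 genes between arms at week 4 and week 12. Array weights raised the anti-miR-33 count from baseline to week 12 to 3473. With the 3′ minus 5′ covariate the counts were 494 in control and 137 in anti-miR-33 animals from baseline to week 12 and 1581 in anti-miR-33 animals from baseline to week 4, and 3 lists passed at baseline. Reversed values with it in anti-miR-33 animals were CAB39 (-0.022), SDHC (-0.03), TKFC (-0.058) and oxidative phosphorylation (-0.044) from baseline to week 12, and SEL1L (-0.014) and SLC37A4 (-0.047) from baseline to week 4. A slope on the 3′ minus 5′ value was called for 2132 of 13634 genes.

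The counts of lists moved most. With an estimated correlation they were 0 in all comparisons except 1 in control animals from baseline to week 12. With no filter 2 lists passed between arms at week 4 and 5 from baseline to week 4 in anti-miR-33 animals. With a stricter filter 0 passed at baseline, and 4 and 2 in control animals from baseline and from week 4 to week 12. Quantile normalization left 3 for the difference in change from week 4 to week 12 and reversed the hepatocyte list from baseline to week 12 (-0.004). Without the week 12 array of control replicate 5 there were 4 at week 12 and 3 in each difference in change to week 12, and 740 genes from week 4 to week 12 in control animals. Without the week 4 array of control replicate 1 there were 4 lists for the difference in change from week 4. The cause of these shifts was not tested. Counts of lists were not recomputed with every probe set, a variance trend, array weights, other blocks or single weeks.

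Leaving out each animal in turn, or week 4 control replicate 1, gave ranges of genes called. To week 12 from baseline they were 516 to 1554 in control animals, lowest without control animals 3 (516) and 5 (661), and 1207 to 2543 in anti-miR-33 animals, lowest without animals 4 (1207), 5 (1357) and 6 (1374). Those from week 4 to week 12 were 576 to 1291 in control animals (604, 609 and 576 without control animals 2, 3 and 5) and 930 to 1826 in anti-miR-33 animals (930, 1072 and 1034 without animals 2, 3 and 5). Those from baseline to week 4 were 1694 to 2549 in control animals and 1531 to 2658 in anti-miR-33 animals (1669 and 1531 without animals 4 and 5). Fewer samples entered these fits. Lists called ranged from 0 to 4 at baseline, 1 to 3 at week 4 (3 without control animal 4 or anti-miR-33 animal 6, 2 without control animal 3 or anti-miR-33 animal 4) and 5 to 12 at week 12 (5 without control animal 5). For the differences in change they ranged from 1 to 4 to week 4 (4 and 1 without anti-miR-33 animals 4 and 5), 4 to 10 to week 12 (10 without control animal 2) and 3 to 10 from week 4 (3 without control animal 5, 4 without control animal 1 or anti-miR-33 animal 6, 5 without anti-miR-33 animal 5). Within arms they were 4 to 7 in control animals from week 4 to week 12 (4 without control animal 1), and 3 to 5 in both arms from baseline to week 4. The acute phase list's difference in change from week 4 ranged from -0.02 to 0.10 and reversed without control animal 5. Dim probe sets, near the filter at 4.459, limit what these arrays can show.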

Other observations

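The changes from baseline to week 4, and the tests of RNA integrity, of a lower share of non-parenchymal cells, of the diet switch and of lasting differences, were chosen after the data were seen.

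By week 4, before the diet switch, the mean of the endothelial list had fallen and that of the interferon list had risen in both arms. Camera called both lists with the preset correlation and not with an estimated one. Only some large changes are named. In control animals EFNB2 fell by 2.05 ± 0.19 (SE), in 6 of 6 animals (limma, adjusted p = 9.55e-09). CETP fell by 1.94 ± 0.21 and KIT fell by 1.71 ± 0.19. The scavenger receptor STAB2 fell by 1.01 ± 0.12 and CLEC4G fell by 1.11 ± 0.15, while FCN2 stood at -1.65 ± 0.17 on 1 probe set and at 0.35, called the other way, on another. Endothelial markers fell in 12 of 16 genes, or 13 adjusted over the list alone, with a mean of -0.69 ± 0.12 (camera, adjusted p = 6.17e-10; adjusted p = 0.243 with an estimated correlation; exact permutation p = 0.0312). Interferon genes rose in 15 of 26, as adjusted over the list alone, with a mean of 0.38 ± 0.07 (adjusted p = 5.32e-09; adjusted p = 0.243 with an estimated correlation), IFI44 by 1.09 ± 0.24 and IFI6 by 0.88 ± 0.11. Stellate cell and fibrosis markers fell in 8 of 17, or 10 adjusted over the list alone (mean -0.38, adjusted p = 3.07e-04; adjusted p = 0.901 with an estimated correlation), among them BGN (-0.69 ± 0.11, with 1 of its others at -0.16) and SPARC (-0.76 ± 0.14). SIRT6, a deacylase and miR-33 target, rose by 0.40 ± 0.07, and ETFDH, of fatty acid oxidation, and FOXO1, of insulin signalling, fell by 0.87 ± 0.16 and fell by 0.75 ± 0.15.

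In anti-miR-33 animals IL6ST fell by 1.79 ± 0.20 (limma, adjusted p = 1.62e-07; other probe sets at -1.14 and 0.09). EFNB2 fell by 1.34 ± 0.19 and CETP by 1.21 ± 0.21. Each gene fell in 6 of 6 animals. Endothelial markers fell in 10 of 16 and rose in 1, or 11 and 1 adjusted over the list alone (mean -0.49 ± 0.10, camera, adjusted p = 3e-06; adjusted p = 0.488 with an estimated correlation), with PECAM1 at -0.73 ± 0.13 (others at 0.01, -0.01 and -0.27) and STAB1 at -0.56 ± 0.11. Interferon genes rose in 7 of 26, or 10 adjusted over the list alone (mean 0.26 ± 0.03, adjusted p = 0.00122; adjusted p = 0.901 with an estimated correlation). Stellate cell and fibrosis markers fell in 5 of 17, or 7 adjusted over the list alone (mean -0.32, adjusted p = 0.00348; adjusted p = 0.926 with an estimated correlation), a call lost without anti-miR-33 animal 3 (-0.23). PSAT1 rose by 1.81 ± 0.34 (other probe set at 0.16) and SELENOT by 1.41 ± 0.26. With the 3′ minus 5′ covariate they were 0.49 and 0.40. In control animals IL6ST stood at -1.46, PSAT1 at 1.66 and SELENOT at 1.00. ABCA1 stood at 0.42 ± 0.16 and did not pass (adjusted p = 0.0607). The 3′ minus 5′ value itself fell by 0.51 ± 0.23 in control and fell by 0.74 ± 0.12 in anti-miR-33 animals (exact permutation p = 0.125 and 0.0312). The fall was larger by ACTB than by GAPDH.

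From baseline to week 4 limma called 2465 genes in control animals, 874 higher and 1591 lower, and 2547 in anti-miR-33 animals, 1100 higher and 1447 lower. The arms shared 494 higher and 974 lower genes, where independent lists would share 70.5 and 168.9, and 0 went in opposite directions. With the baseline arrays in common, the changes to week 4 and to week 12 shared 141 higher and 544 lower genes in control animals (24.9 and 106 if independent, 3 opposite). In anti-miR-33 animals they shared 332 and 578 (75.8 and 136.3 if independent, 9 opposite), and part of these overlaps comes from the shared arrays. A batch of the week 4 arrays and week 4 cannot be told apart.

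The endothelial markers were lower at week 12 than at baseline in both arms. A difference in RNA integrity between the array sets is argued against as the whole cause, since 74.8% of the fall was kept with the 3′ minus 5′ covariate in the arm that kept less. A lower share of all non-parenchymal cells would lower macrophage markers too, but these changed by 0.07 ± 0.05 in control and -0.07 ± 0.07 in anti-miR-33 animals, above the bound set from the endothelial fall by 0.43 ± 0.06 and 0.277 ± 0.032 (SE); stellate cell and fibrosis markers did fall, with means of -0.37 ± 0.09 and -0.47 ± 0.10, so a lower share of endothelial and stellate cells together stays open. Unless a week 4 batch set those values, the diet switch after week 4 is argued against as the whole cause, since the markers stood at -0.69 ± 0.12 in control and -0.49 ± 0.10 in anti-miR-33 animals by week 4, or 93.1% and 70.8% of the week 12 change, and a part played by the diet stays open. A fall of endothelial transcripts with time in the study, or with repeated biopsies or the injections that both arms had, may be an open hypothesis and was not tested.

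The genes of smallest p between arms at week 12 might differ between these animals for reasons that predate treatment. For the 20 of smallest p, the median difference, turned to the week 12 sign, was 0.18 at baseline, 0.34 at week 4 and 0.45 at week 12. The baseline median was 39.1% of that at week 12, with a bootstrap interval from 24.9 to 62.8 over 1000 draws of animals. The genes were picked on the same week 12 values, which tends to enlarge the week 12 median and lower this percent. The draws kept the genes and their signs fixed, so the interval does not cover that choice. The sign was that of week 12 for 15 of the 20 at baseline and 17 at week 4. Single genes, named after their values were seen, lay apart. Those with an unadjusted limma p under 0.05 at baseline were ECRG4 (-0.73), FGF13 (-0.66), GRK3 (-0.55), SULT1A1 (0.46), CLHC1 (0.45), SELENOW (0.41), LITAF (-0.34) and HMGB3P1 (0.19). PIN4 (-0.003) and ATP2B2 (-0.002) lay near 0 at baseline. Lasting differences between animals were thus neither excluded nor shown to account for the 20 genes as a set.

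Across the 12 baseline arrays, the mean of the fatty acid synthesis genes fell with the 3′ minus 5′ value, with a Pearson r of -0.839 (permutation p = 7e-04, two-sided; adjusted p = 0.0084 over 12 relations tested by permutation) and a Spearman rho of -0.832 (permutation p = 0.0012). Without the 2 arrays farthest from the median r was -0.71. At week 4 and week 12 r was -0.436 and 0.081 (permutation p = 0.158 and 0.803). Of 4919 probe sets above the filter that named no gene or several, limma called 0 between arms or in the differences in change, with 104 to 259 at an unadjusted p under 0.05. Over time it called from 190, in control animals from baseline to week 12, to 728, in anti-miR-33 animals from baseline to week 4.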
